A study of Caenorhabditis elegans with 12 samples.

How the data were processed

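Total RNA of whole synchronized N2 Bristol adults was measured on 12 Affymetrix arrays. Per the labels' protocols, embryos were plated and grown at 23 °C for 2.5 days, the adults were shifted to 17 °C, and amplified cDNA was fragmented and labelled with biotin using a NuGEN kit. Animals were taken just before the shift (0 h, n = 4) and 1 h (n = 2), 2 h (n = 2) and 4 h (n = 4) after it, and each array is named here by its time and replicate number. The deposited values are log2 signals per probe set, which the authors made with RMA, per the submitters' processing notes, with no version given. That their base is 2 was inferred from that method and from the range of the values. Any further filter, and a genome build, are not given in the sources used here. The sorted values of the 12 arrays differed from their mean by at most 0.11, so the arrays had been brought close to one distribution before deposition. No scanner files were used here, so signal over background was not assessed.

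All 22548 probe sets were tested, since 0 control probe sets had to be removed. Gene names came from the platform annotation, which gives 1 symbol for 20766 probe sets and several for 887, while 895 are unnamed here. Of these names, 20701 probe sets matched the WBcel235 gene table by gene identifier, which changed 0 symbols, and no coordinates are printed because no build is named. Genes were named only from probe sets with 1 symbol, and each of the 17118 genes was represented by its probe set with the highest mean signal (2981 genes had more than 1). Heat-inducible probe sets with several symbols are described by the number of members they cover.

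One linear model with a mean per time was fitted over all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with default settings, 8 residual and 5.03 prior degrees of freedom). The times with 2 arrays thus take their spread from all groups. Two-sided p-values were adjusted by Benjamini-Hochberg over the probe sets of a comparison, with a threshold of 0.05. The comparisons were 1 h, 2 h and 4 h with 0 h, 2 h with 1 h, 4 h with 2 h, and a moderated F test over the 3 changes from 0 h.

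The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. For each comparison with 0 h the rule names the 10 largest rises and 10 largest falls among called genes whose every array lay outside the range of the 0 h arrays, or the 5 smallest p-values where none passed. It adds up to 4 called members of each list, or up to 2 members by smallest p where none passed, and a fixed set of genes of heat shock, thermosensation, lipid desaturation, yolk, eggshell and cold response. The fixed gene daf-21 was measured under its symbol hsp-90, and aip-1 was not measured by a single-gene probe set. Genes named for the step from 2 h to 4 h were all those called there, and so were chosen after their values were seen.

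Each of 41 lists was tested with camera (preset correlation 0.01) on the representative probe sets, adjusted over the lists of a comparison, with an estimated correlation and fry beside it. Fry's directional test asks whether members move on balance one way and its mixed test whether they change in either direction; neither compares a list with other genes. The lists covered heat-inducible, cytosolic, endoplasmic reticulum and mitochondrial chaperones, fatty acid synthesis, beta-oxidation, fasting, the thermotaxis circuit, neuropeptides, insulin-like peptides, insulin targets and dod genes. They also covered vitellogenins, eggshell, sperm, germline, early zygotic genes, histones, collagens, moulting, ribosome, proteasome, oxidative phosphorylation, C-type lectins, lysozymes, cytochrome P450, glutathione S-transferases, UDP-glucuronosyltransferases, nuclear hormone receptors, osmotic genes, Y-box genes, cold and iron genes, F-box genes and chemoreceptors. Markers of muscle, pharynx, intestine, neurons, hypodermis, coelomocytes and the uterus, spermatheca and vulva completed them.

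Arrays of 0 h and 4 h with the same replicate number deviated together from their group means (r = 0.169 to 0.314 in 4 pairs, against -0.29 to 0.147 for other numbers), and 8 of 8 arrays correlated best with their own number. The numbers were therefore taken to pair the 0 h and 4 h arrays. They also formed 2 blocks. Different numbers correlated at 0.0362 to 0.147 within 1 and 2 or within 3 and 4, and at -0.29 to -0.122 across the blocks. What sets the blocks apart was not tested. The pairing comes from these values, not from the labels. Arrays of 1 h and 2 h with the same number correlated at 0.185, and neither time correlated above 0.1 with the 0 h array of its number (-0.075 to 0.00773).

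The fit was tested on simulated data with 22548 probe sets and 50 seeded changes of each size per comparison. Of changes of 0.5 log2 units, 48% were recovered at 1 h, 52% at 2 h and 66% at 4 h. Of changes of 1 log2 unit, 94%, 100% and 100% were recovered. False calls were 11 of 182 at 1 h, 17 of 193 at 2 h and 10 of 193 at 4 h. Each probe set was drawn independently with the spread of the fit, so these rates may not hold for the real arrays. Each result was recomputed with quantile normalization, centred arrays, filters on dim probe sets, without probe sets that can cross-hybridise, with trend and robust variances, with array weights, with the replicate number as a fixed or random block, and without each array in turn. The 4 h comparison was also run on its 8 arrays alone, with and without the block, and with a minimum change of 1.5-fold. The lists were also run with other ways of taking probe sets to genes. Probe sets that can cross-hybridise were taken as all those with the suffix _x_at or _s_at, which include probe sets with 1 symbol. Where dim or cross-hybridising probe sets were left out, genes represented by them left their lists and took no other probe set. Lists were then shorter, so a call lost there is not by itself a sign of cross-hybridisation. Other splits of the 8 arrays of 0 h and 4 h were counted. Unchanged groups, the 0 h group included, were simulated 100 times with each probe set drawn independently. This was done without and with a correlation of 0.28, estimated from these arrays, between 0 h and 4 h arrays of a number. Rises at 2 h were also checked on arrays that took no part in choosing the probe sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.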

Results

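Gene expression was measured on 12 Affymetrix arrays of total RNA from whole synchronized adults of the nematode Caenorhabditis elegans, strain N2 Bristol, the standard wild type. The animals were cultivated at 23 °C and then moved to 17 °C. Arrays were made just before the move (0 h, n = 4) and 1 h (n = 2), 2 h (n = 2) and 4 h (n = 4) after it. The comparisons ask which transcripts differed after the move to the cooler temperature, and when. Per the labels, a fraction of the animals also went to a thermotaxis assay, a test of movement in relation to temperature, which was not used here. No array came from animals kept at 23 °C for the same hours, so the comparisons with 0 h hold time and handling as well as temperature. The labels do not say that replicates came from separate cultures, and the p-values below measure only the spread between these samples.

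Expression is given in log2 units. That the base is 2 rests on the usual output of RMA, the summary method the submitters name, and on the range of the values, from 1.508 to 14.36. Array medians lay between 5.502 and 5.571 and lower quartiles between 3.53 and 3.64. Signal over background was not assessed, so the size of a change to or from levels near the lower quartile is uncertain. Across probe sets, the groups of oligonucleotides that each read a transcript, Pearson's r between arrays was 0.994 to 0.998. The standard deviation of the difference between arrays of the same time was 0.188 to 0.266 over 14 pairs. The number of arrays limits the precision of every value below. On the first principal component (21.4% of the variance), the 0 h arrays lay from -16.3 to -9.31 and the 4 h arrays from 1.33 to 12.7. The 1 h arrays lay at -10.4 and 6.22 and the 2 h arrays at 4.72 and 21.2. On the third component (12%), 0 h and 4 h arrays of replicates 1 and 2 lay from -7.93 to -1.42. Those of replicates 3 and 4 lay from 7.49 to 15.3. The 1 h and 2 h arrays, all of replicates 1 and 2, lay from -12.4 to -1.46. Their comparisons with all 4 arrays at 0 h thus also hold this difference between replicates.

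At 4 h, endu-2, which encodes an EndoU-family endoribonuclease, was 4.40-fold higher than at 0 h (9.21 ± 0.0983 against 7.07 ± 0.397, SD, n = 4 each). Its log2 change was 2.14 (SE 0.179, limma adjusted p = 7.85e-05). The potassium channel gene kqt-2 rose by 1.98 (SE 0.154, adjusted p = 6.6e-05) and pmp-1, a peroxisomal ABC transporter gene, by 1.21 (SE 0.142, adjusted p = 0.000574). The metallothionein gene mtl-1 fell by 1.51 (SE 0.174, adjusted p = 0.000525), from 9.11 ± 0.168 to 7.59 ± 0.389. The UDP-glucuronosyltransferase gene ugt-63 fell by 1.54 (SE 0.127, adjusted p = 7.85e-05), and the cytochrome P450 gene cyp-37B1 fell by 1.57 (SE 0.22, adjusted p = 0.00209). Over the arrays as a whole, 518 of 22548 probe sets passed, 301 higher and 217 lower, in 425 genes of which 247 rose and 178 fell. The median size of the called changes was 0.55 log2 units, and 218 of the 518 were at least 1.5-fold.

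Among the 10 largest rises, C10C5.5 (1.501), Y37H2A.14 (1.53), C08E8.4 (1.32) and K05B2.4 (1.29) stood beside fbxc-58, an F-box gene (1.22), M01G12.9 (1.19) and Y51A2D.13 (1.17). Among the 10 largest falls were F57B1.6 (-1.63), the amine N-methyltransferase gene anmt-3 (-1.48), Y26D4A.21 (-1.45), T05E7.1 (-1.35), the small heat-shock gene hsp-16.2 (-1.34), ZC204.12 (-1.27) and C50A2.3 (-1.21). Adjusted p-values of these 20 genes ran from 5.9e-05 (Y26D4A.21) to 0.0096 (C08E8.4). By the rule that chose them, each of the 4 arrays at 4 h lay outside the range of the 0 h arrays. Of the 425 called genes, 422 were separated in this way, and 9.36% of all genes were, against 2.86% by chance. The 20 calls held without any single array. The call of kqt-2 rests on 1 of its 3 probe sets, since the others changed by 0.27 (adjusted p = 0.17) and 0.38 (adjusted p = 0.0658).

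**Figure D1:**
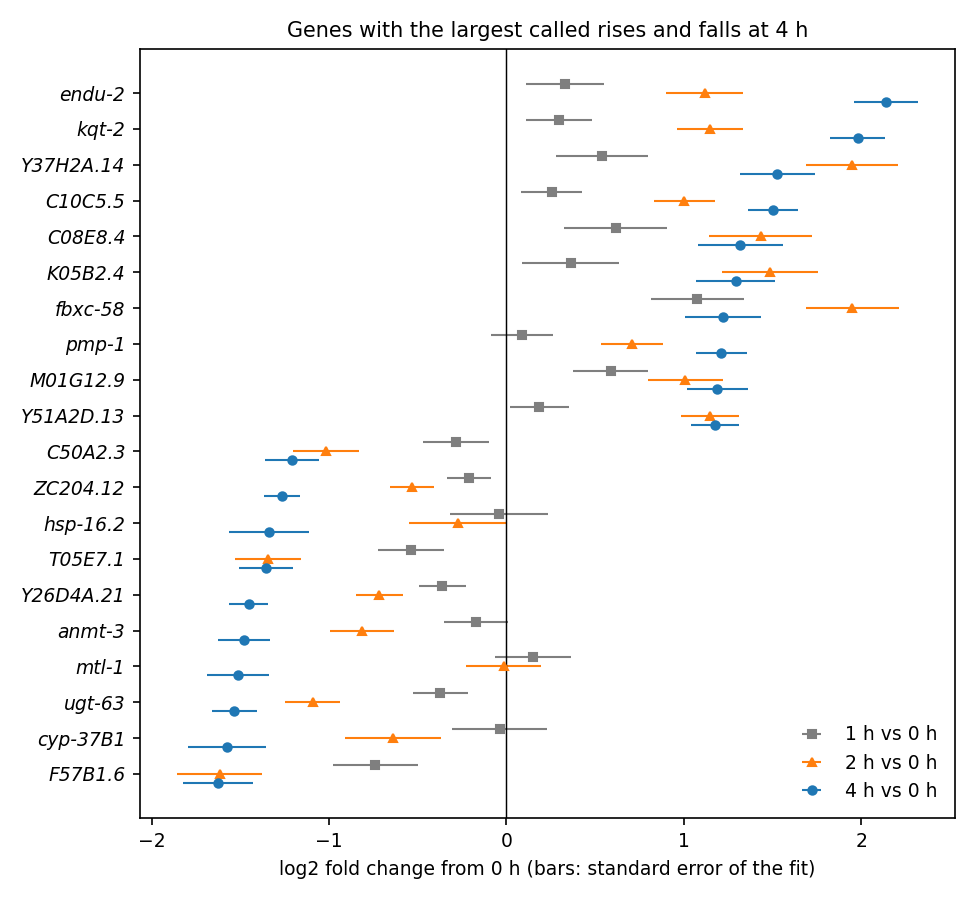
Log2 fold change from 0 h (horizontal axis) of the 10 largest called rises and the 10 largest called falls at 4 h, at 1 h (grey squares), 2 h (orange triangles) and 4 h (blue circles), with bars for the standard error of the fit. At 4 h the changes ran from -1.63 (F57B1.6) to 2.14 (endu-2), while at 1 h mtl-1 lay at 0.15 and hsp-16.2 at -0.04.

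Heat-inducible chaperone transcripts were lower after 4 h at 17 °C. These small heat-shock proteins and inducible HSP70 proteins bind unfolded proteins and are made on heat stress. Probe sets that the annotation assigns to 2 hsp-16 members each fell by 2.79 (SE 0.258, adjusted p = 0.000127) and by 2.55 (5.87-fold, SE 0.222, adjusted p = 0.000108). The first went from 6.33 ± 0.554 to 3.55 ± 0.461 and the second from 7.57 ± 0.335 to 5.02 ± 0.509 (SD, n = 4 each). The gene hsp-16.2 fell (log2 change -1.34, adjusted p = 0.00689), as did hsp-16.41 (log2 change -0.84, adjusted p = 0.00917). The 4 h means of the first shared probe set (3.55), hsp-16.2 (3.74) and hsp-16.41 (2.67) lay near or under the lower quartile of the arrays, which leaves the size of these falls uncertain. A pair of probe sets, both assigned to the same 2 HSP70-family members, fell by 0.88 (adjusted p = 0.0018) and 0.76 (adjusted p = 0.000389). The gene hsp-70 itself changed by -0.34 and missed the threshold (adjusted p = 0.0729). The 4 h means of the pair (3.82 and 2.55) and of hsp-70 (3.22) were as low, and the second of the pair (3.30) and hsp-70 (3.56) were already there at 0 h, so the size of these changes is uncertain too. In all, 6 of the 7 heat-inducible probe sets fell at 4 h, 2 of 7 fell at 2 h, and 0 of 7 passed at 1 h in limma, where 3 had an unadjusted p under 0.05. These counts hold the shared HSP70-family members through 2 probe sets. The 2 falls at 2 h were those of this pair (-1.14 and -0.58). No hsp-16 probe set passed in limma at 2 h (adjusted p from 0.0978 to 0.744).

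**Figure D2:**
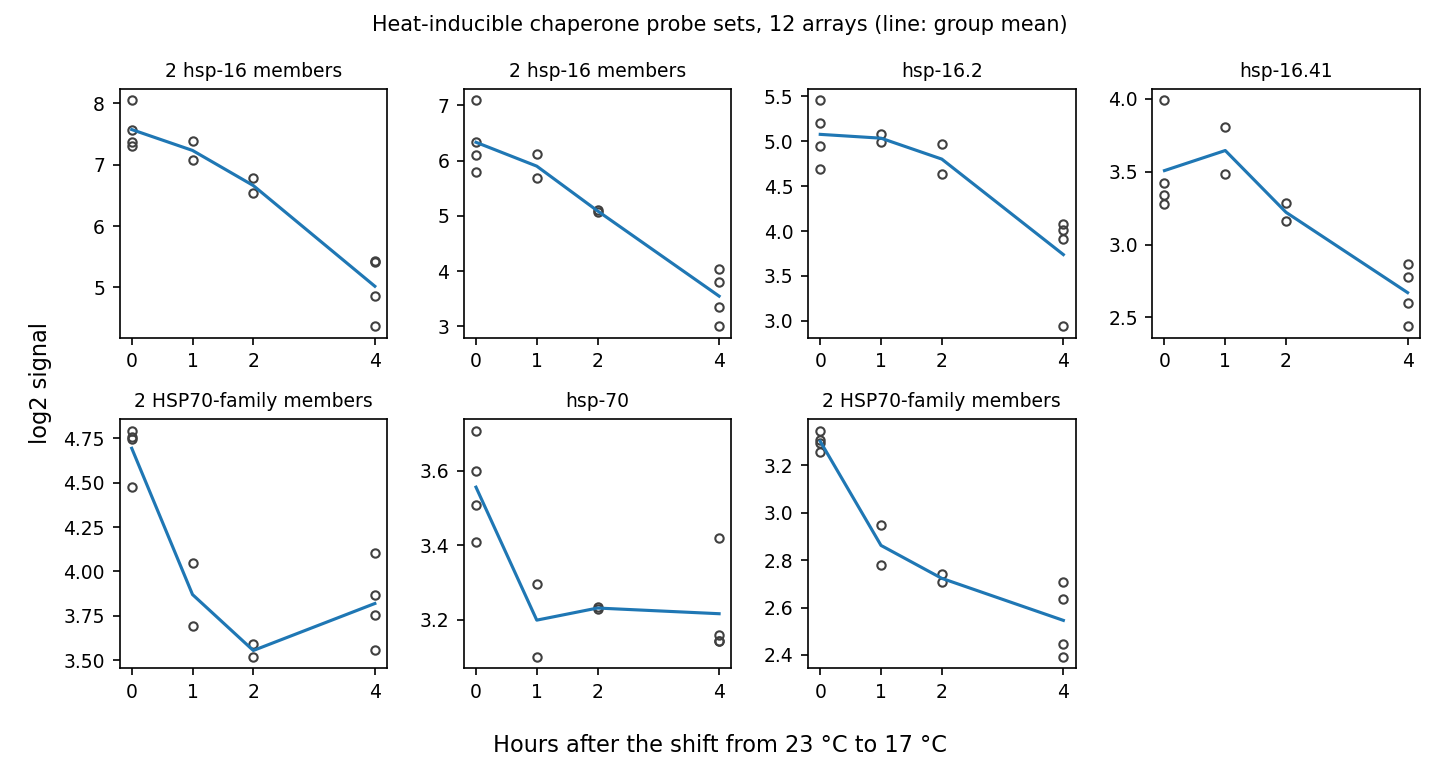
Log2 signal (vertical axis) of the 7 heat-inducible chaperone probe sets on each of the 12 arrays (circles) against hours after the shift, with a line through the group means. The 4 panels of the hsp-16 family are lowest at 4 h, and the panels of HSP70-family members reach levels below all 0 h arrays by 1 h.

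The list of single-gene heat-inducible chaperones held 3 measured members, of which 0 rose, 2 fell and 1 did not pass (3 fell when adjusted over the list alone). As a set it lay below the other genes (camera adjusted p = 7.63e-05), with adjusted p = 0.0654 with an estimated correlation and 0.0012 in fry's directional test. Of 31 constitutive cytosolic chaperones, 0 passed in limma and 1 when adjusted over the list alone, though 28 lay below 0 with a median change of -0.07. Examples were unc-23 at -0.33 (adjusted p = 0.0593) and cct-3 at -0.26 (adjusted p = 0.168). The set test called the list lower (camera adjusted p = 0.00551), with adjusted p = 0.0962 with an estimated correlation and 0.00233 in fry's directional test. Without probe sets that can cross-hybridise the camera adjusted p was 0.102, with a mean change of -0.102 against -0.093 for the whole list. No member passed among 18 chaperones of the endoplasmic reticulum (hsp-3 -0.19, camera adjusted p = 0.6) or 11 mitochondrial chaperones and proteases (dnj-21 -0.17, camera adjusted p = 0.617). The heat-shock factor gene hsf-1 (0.11, adjusted p = 0.621), its regulators hsb-1 (-0.06), ddl-1 (-0.10) and ddl-2 (-0.01), and the chaperone genes hsp-1 (-0.04) and hsp-90 (-0.08) did not pass at any time.

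Called genes on the beta-oxidation list, which includes all acyl-CoA synthetase genes of the acs family, rose more often than they fell at 4 h. Of 54 measured genes of peroxisomal and mitochondrial beta-oxidation, 6 rose, 1 fell and 47 did not pass, with 14 past the threshold when adjusted over the list alone. The enoyl-CoA hydratase gene ech-9 rose by 0.98 (SE 0.159, adjusted p = 0.00485), the acyl-CoA synthetase genes acs-14 and acs-17 by 0.57 and 0.56, and maoc-1, of peroxisomal beta-oxidation, by 0.40 (adjusted p = 0.00983). The set test called the list higher (camera adjusted p = 0.00808), with adjusted p = 0.234 with an estimated correlation and 0.0213 in fry's directional test. The call was also lost without the dimmer 50% of probe sets (camera adjusted p = 0.0709). Of 23 genes of fatty acid desaturation and synthesis, 1 rose and 2 fell (3 when adjusted over the list alone, camera adjusted p = 0.694). The stearoyl-CoA desaturase gene fat-6 fell by 0.64 (SE 0.141, adjusted p = 0.0305), the elongase gene elo-5 fell by 0.44 (adjusted p = 0.0426) and elo-2 rose by 0.48 (adjusted p = 0.0443). These 3 calls were lost without any of 4, 9 and 8 single arrays, with adjusted p up to 0.0922, 0.13 and 0.119, and that of fat-6 also with the 8 arrays of 0 h and 4 h alone (0.0547). The other desaturase genes fat-7 (0.62, adjusted p = 0.205) and fat-5 (0.08, adjusted p = 0.927) and the membrane fluidity gene paqr-2 (0.05) did not pass. Among 14 fasting response genes 0 passed and 4 did when adjusted over the list alone (lipl-2 -0.56, adjusted p = 0.0854).

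Of 73 cytochrome P450 genes at 4 h, 0 rose, 7 fell and 66 did not pass (9 when adjusted over the list alone), with cyp-37B1 first, then cyp-25A1 (-0.54, adjusted p = 0.0247), cyp-29A2 (-0.51, adjusted p = 0.012) and cyp-29A3 (-0.43, adjusted p = 0.0196). Of 64 UDP-glucuronosyltransferase genes, 2 rose, 5 fell and 57 did not pass, and 20 passed when adjusted over the list alone. Besides ugt-63, the genes ugt-53 (-1.07, adjusted p = 0.00051), ugt-43 (-0.68) and ugt-17 (-0.49) fell. Neither list was called by the set test (camera adjusted p = 0.285 and 0.175). Fry's directional test called the UDP-glucuronosyltransferase list (adjusted p = 0.0177) but not the cytochrome P450 list (0.0855). Its mixed test called both (adjusted p = 1.24e-09 each), as it did 20 of the 41 lists at 4 h. Of 59 glutathione S-transferase and redox genes, 2 rose and 1 fell (5 when adjusted over the list alone, camera adjusted p = 0.422): gst-22 rose by 0.79, the autophagy receptor gene sqst-1 by 0.65, and gpx-7 fell by 0.36. The glycerol-3-phosphate dehydrogenase gene gpdh-1, known from the osmotic stress response, fell by 0.88 (adjusted p = 0.00348) as 1 of 12 osmotic and trehalose genes (2 when adjusted over the list alone, camera adjusted p = 0.617). With the replicate number as a block, cyp-25A1 was not called over the 12 arrays (adjusted p = 0.0571) or the 8 arrays of 0 h and 4 h (0.0782), nor gpx-7 over the 8 (0.0511). Without any single array of 0 h or 4 h, 3 to 5 cytochrome P450 genes fell instead of 7. Without some single arrays, cyp-25A1 (adjusted p up to 0.083), cyp-29A3 (0.0657), sqst-1 (0.0795) and gpx-7 (0.148) were not called.

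Intestine markers lay mostly above 0 at 4 h, with called members in both directions. Of 13 measured, 2 rose, 1 fell and 10 did not pass (7 passed when adjusted over the list alone). In all, 10 lay above 0 and 3 below, with a median of 0.17. The peptide transporter gene pept-1 rose by 0.91 (SE 0.0838, adjusted p = 0.000127), from 6.998 ± 0.0762 to 7.91 ± 0.0843 (SD, n = 4 each). The cathepsin B-like protease gene cpr-1 rose by 1.03 (adjusted p = 0.0138) and vha-6, an apical proton pump subunit gene, fell by 0.30 (adjusted p = 0.0421). The set test called the list higher (camera adjusted p = 0.00428), with adjusted p = 0.451 with an estimated correlation and 0.021 in fry's directional test. The call of cpr-1 was lost without replicate 3 or replicate 4 at 0 h (adjusted p up to 0.0519), and that of vha-6 without any of 11 arrays (adjusted p up to 0.127). Of 63 lysozyme and antimicrobial peptide genes, 3 rose and 1 fell (8 when adjusted over the list alone, camera adjusted p = 0.0865): lys-4 rose by 0.69 (adjusted p = 0.00202), lys-6 by 0.63 and ilys-4 by 0.38, while the saposin-like gene spp-1 fell by 0.41. Among 220 C-type lectin genes 2 rose and 3 fell (5 when adjusted over the list alone, camera adjusted p = 0.6), such as clec-223 (0.52) and clec-56 (-0.49). Without some single arrays ilys-4, spp-1, clec-223 and clec-56 were not called (adjusted p up to 0.0936, 0.119, 0.0856 and 0.0998), and the other probe set of spp-1 changed by -0.07. With the replicate number as a block, clec-223 and clec-56 were not called over the 12 arrays (adjusted p = 0.0514 and 0.0562) or the 8 of 0 h and 4 h (0.0774 and 0.0536), nor ilys-4 over the 8 (0.0649).

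Transcripts of the thermotaxis circuit were largely below the threshold at 4 h. Of 25 measured genes, 0 rose and 1 fell (1 when adjusted over the list alone, camera adjusted p = 0.694): hen-1, which encodes a secreted protein needed for integrating sensory cues, fell by 0.67 (SE 0.121, adjusted p = 0.0095), from 6.57 ± 0.222 to 5.90 ± 0.201 (SD, n = 4 each). The guanylyl cyclase genes of the thermosensory neuron AFD, gcy-8 (0.07), gcy-18 (0.03) and gcy-23 (-0.02), the channel gene tax-4 (-0.08) and nhr-69 (0.22) did not pass at any time. RNA came from whole animals, so a change confined to such a neuron could be missed. At 0 h gcy-8 lay at 3.76 to 3.91, near the lower quartile of the arrays, where the size of a change is uncertain. The insulin-like peptide gene ins-34 rose by 0.60 (adjusted p = 0.00473), 1 of 24 in its list (1 when adjusted over the list alone), whose median (-0.04) and set test lay below 0 and whose mean (0.01) lay above (camera adjusted p = 0.89). No member passed among 86 neuropeptide genes (nlp-31 0.68, adjusted p = 0.0557, list camera adjusted p = 0.6), and 1 of 16 pan-neuronal markers rose, aex-3 by 0.45 (adjusted p = 0.0138, 1 when adjusted over the list alone, list camera adjusted p = 0.386), with its other probe set at 0.38 (adjusted p = 0.118).

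Reproductive and cuticle transcripts changed little gene by gene. Of 79 sperm genes 0 rose and 1 fell (ssp-10, -0.52, adjusted p = 0.0071), and 1 passed when adjusted over the list alone, yet 64 lay below 0. The set test called the list lower (camera adjusted p = 0.00551), with adjusted p = 0.643 with an estimated correlation and 0.337 in fry's directional test. That call was lost without replicate 2 or replicate 4 at 0 h and without replicate 2 or replicate 3 at 4 h (adjusted p = 0.0539, 0.169, 0.112 and 0.103), and without probe sets that can cross-hybridise (0.137). The median of the list relative to each gene's mean spread from -0.08 to 0.19 within the 0 h arrays and from -0.15 to 0.07 within the 4 h arrays. Within replicate numbers 1 to 4 it went from -0.025 to -0.039, from 0.186 to -0.142, from -0.081 to -0.154 and from 0.101 to 0.068, lower at 4 h each time. Of 145 cuticle collagen genes 0 rose and 2 fell (1 when adjusted over the list alone): col-158 by -0.45 (adjusted p = 0.00569) and col-118 by -0.31 (adjusted p = 0.0443), while 127 lay below 0 with a median of -0.11. The call of col-118 was lost without any of the 8 arrays of 0 h and 4 h (adjusted p up to 0.133), and with the replicate number as a block over the 12 arrays (0.063). This list had the smallest p of the 41 set tests at 4 h (camera adjusted p = 2.76e-06). Its adjusted p was 0.454 with an estimated correlation and 0.0625 in fry's directional test. Among 47 early zygotic genes 2 fell, sdz-6 (-1.11, adjusted p = 0.0105) and sdz-24 (-0.90, adjusted p = 0.000304), with 3 when adjusted over the list alone (camera adjusted p = 0.694).

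Several lists had 0 members past the threshold at 4 h in limma: 5 vitellogenins (vit-2 0.00, vit-6 0.01, camera adjusted p = 0.927), 33 eggshell and oocyte-to-embryo genes (cbd-1 0.01, 0.204) and 35 germline and meiosis genes (syp-4 0.16, 0.393). The same held for 26 histones (his-37 -0.25, camera adjusted p = 0.193), 58 ribosomal proteins (rpl-4 0.12, 0.816), 31 proteasome subunits (rpn-1 0.12, 0.927) and 29 oxidative phosphorylation genes (asb-2 -0.19, 0.0978). It held for 5 genes with a Y-box cold-shock domain (lin-28 -0.03, camera adjusted p = 0.904), 6 dod class II genes (dod-19 -0.28, 0.352), 17 body wall muscle markers (mup-2 -0.27, 0.175) and 16 pharynx markers (tnt-4 -0.14, 0.927). Finally it held for 10 hypodermis markers (col-19 -0.23, camera adjusted p = 0.816), 4 coelomocyte markers (unc-122 0.22, 0.946) and 9 uterus, spermatheca and vulva markers (cdh-3 0.47, 0.694). Adjusted over the list alone, 1 uterus, spermatheca and vulva marker passed and 0 members of the others did. Of 12 insulin pathway targets mtl-1 fell and 0 rose (2 when adjusted over the list alone, camera adjusted p = 0.25). In none of the 3 comparisons with 0 h did a set test stay past the threshold with an estimated correlation. At 4 h that estimate was under the preset of 0.01 for heat-inducible (-0.097) and cytosolic chaperones (-0.0018), so correlated members did not end those calls. It was above the preset for the other called lists, beta-oxidation (0.015), sperm (0.19), collagens (0.1) and intestine (0.13).

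The count at 4 h fell to 324 without replicate 3 at 4 h, to 344 without replicate 2 at 0 h and to 345 without replicate 3 at 0 h. Named calls at 4 h numbered 74, of which 54 held without any single array.

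At 2 h, the 10 largest rises were led by C06B3.7 (2.01, SE 0.306, adjusted p = 0.00666), the tetraspanin gene tsp-2 (1.97, SE 0.211, adjusted p = 0.000992) and fbxc-58 (1.95). The change of C06B3.7 was 1.23 without replicate 2 at 2 h (adjusted p = 0.0499) and 2.78 without replicate 1, where tsp-2 ran from 1.66 to 2.29 without any single array. The gene F53B2.8 was 3.35-fold higher than at 0 h (10.06 ± 0.202, n = 2, against 8.32 ± 0.0929, n = 4, SD, adjusted p = 0.000416). The ceramide glucosyltransferase gene cgt-1 rose by 1.63, gst-22 by 1.56, the galectin gene lec-11 by 1.55 and the acyltransferase-like gene oac-6 by 1.49. C40H1.7 had the largest fall (-2.03, SE 0.251, adjusted p = 0.0022), and K02E7.6 fell by 1.35 (SE 0.106, adjusted p = 0.00011). The cuticlin-like gene cutl-18 fell by 1.503, gpdh-1 by 1.28, the ammonium transporter gene amt-4 by 1.26 and ugt-63 by 1.09. In total 218 of 22548 probe sets passed, 137 higher and 81 lower, in 182 genes, of which 121 rose and 61 fell. All 182 genes had both 2 h arrays outside the range of the 0 h arrays, as had 21.9% of all genes, against 13.3% by chance.

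**Figure D3:**
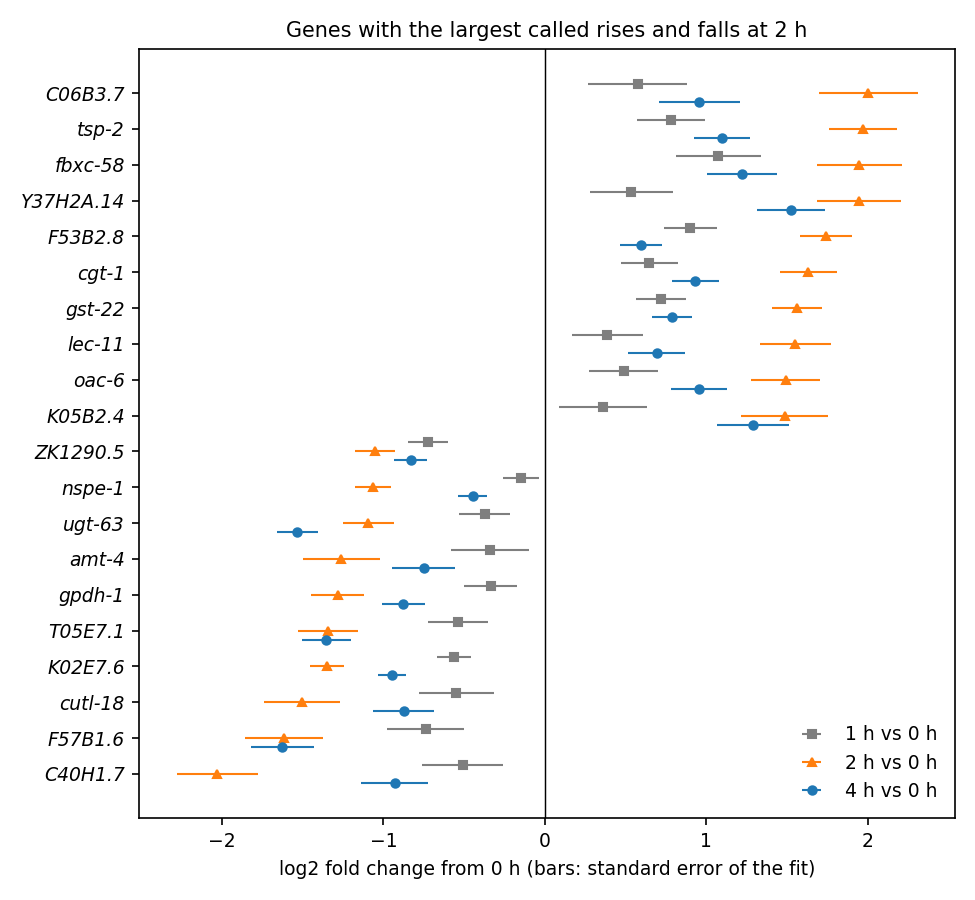
Log2 fold change from 0 h (horizontal axis) of the 10 largest called rises and the 10 largest called falls at 2 h, at 1 h (grey squares), 2 h (orange triangles) and 4 h (blue circles), with bars for the standard error of the fit. F53B2.8 was at 1.74 at 2 h and 0.60 at 4 h, whereas F57B1.6 lay near -1.62 at both times.

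A bZIP transcription factor gene and a pair of protease genes rose at 2 h in the cold-response list. The list joins the bZIP transcription factor gene zip-10, protease genes tied to it and ferritin-related genes. Of its 8 measured members 3 rose and 0 fell (3 when adjusted over the list alone): zip-10 by 1.29 (2.45-fold, SE 0.206, adjusted p = 0.00867), the aspartyl protease gene asp-17 by 1.22 (SE 0.216, adjusted p = 0.0156) and the cathepsin B-like gene cpr-3 by 1.21 (SE 0.113, adjusted p = 0.000416). Of the 8, 5 lay above 0 and 3 below, and the median of 0.08 lay far under the mean of 0.43. The set test called the list higher (camera adjusted p = 0.0157), with adjusted p = 0.143 with an estimated correlation and 0.00276 in fry's directional test. Without probe sets that can cross-hybridise the camera adjusted p was 0.264, with a mean change of 0.396. The ferritin gene ftn-1 was at -0.20 (adjusted p = 0.62) at 2 h, did not pass at any time, and neither did lips-11 (0.28 at 2 h). At 4 h 1 of the 8 had risen, cpr-3 by 0.79 (adjusted p = 0.000526), with zip-10 at 0.24 (adjusted p = 0.658), 2 when adjusted over the list alone and camera adjusted p = 0.175. Without replicate 1 at 2 h zip-10 was not called (adjusted p = 0.0688), and without replicate 2 at 2 h asp-17 was not (adjusted p = 0.178).

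Lysozyme and antimicrobial peptide genes gave the smallest p of the 41 set tests at 2 h (camera adjusted p = 3.56e-07), with adjusted p = 0.143 with an estimated correlation. Of 63 measured members 4 rose, 0 fell and 59 did not pass, and 10 rose when adjusted over the list alone: lys-7 by 1.27 (adjusted p = 0.0488), irg-2 by 0.95 (adjusted p = 0.00831), lys-3 by 0.87 and lys-6 by 0.70. The call of irg-2 was lost without replicate 2 at 2 h alone (adjusted p = 0.167). Those of lys-7, lys-3 and lys-6 were lost without any of 9, 7 and 5 single arrays, 0 h arrays and replicate 2 at 2 h among them (adjusted p up to 0.313, 0.542 and 0.294). With trend and robust variances lys-7 was not called (0.0885), nor lys-3 with the replicate number as a block (0.0555). Neuropeptide genes were called higher as a set (camera adjusted p = 5.79e-06), with adjusted p = 0.143 with an estimated correlation. Of 86 members 62 lay above 0 with a median of 0.15, but 0 passed in limma or when adjusted over the list alone (flp-18 0.60, adjusted p = 0.0914, and flp-16 0.42, adjusted p = 0.0934). Pan-neuronal markers were not called as a set (camera adjusted p = 0.0683), with 12 of 16 above 0, a median of 0.12 and 1 past the threshold, 2 when adjusted over the list alone. That gene, aex-3 (0.51, adjusted p = 0.0402), was lost without any 1 of the 4 arrays at 0 h, replicates 2 and 3 at 4 h and both 2 h arrays (adjusted p up to 0.472) and after quantile normalization (0.0521). Insulin pathway targets had 0 of 12 past the threshold and 3 when adjusted over the list alone (dod-3 0.97, adjusted p = 0.0622). Body wall muscle markers had 0 of 17 by either count (unc-54 0.35, adjusted p = 0.443). Both lists were called higher (camera adjusted p = 0.0257 and 0.0341), with adjusted p = 0.256 and 0.615 with an estimated correlation, and neither without replicate 2 at 2 h (0.409 and 0.698) or without probe sets that can cross-hybridise (0.648 and 0.458), nor muscle markers without replicate 3 at 0 h (0.0982). Constitutive chaperones were called lower with 0 of 31 past the threshold or when adjusted over the list alone (hsp-90 -0.23, adjusted p = 0.185, camera adjusted p = 0.0459), with adjusted p = 0.152 with an estimated correlation, 0.153 after quantile normalization, 0.421 without probe sets that can cross-hybridise, 0.271 with the replicate number as a block, and up to 0.167 (without replicate 1 at 2 h) over the 6 single arrays whose loss ended the call.

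Body wall muscle markers differed between arrays of the same time. Their median relative to each gene's mean was 0.25 in replicate 2 at 1 h and 0.20 in replicate 2 at 2 h, against -0.07 and 0.04 in replicate 1 at those times. It was -0.22 and -0.12 in replicates 1 and 2 at 4 h, against -0.03 and -0.02 in replicates 3 and 4. In the 0 h arrays it lay between -0.06 and 0.05.

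Metabolic groups at 2 h had few members past the threshold. Of 73 cytochrome P450 genes 0 rose and 3 fell (4 when adjusted over the list alone): cyp-13A2 (-0.72, adjusted p = 0.00919), cyp-29A2 (-0.68) and cyp-14A2 (-0.57). Of 54 beta-oxidation genes 2 rose, ech-7 by 0.92 (adjusted p = 0.0272) and acs-17 by 0.69 (adjusted p = 0.00922, its other probe set adjusted p = 0.0529), with 7 when adjusted over the list alone. Of 59 glutathione S-transferase and redox genes 2 rose, gst-22 and sqst-1 (1.04, adjusted p = 0.00919), in a list whose median (-0.02) lay below 0 while its mean (0.05) and its set test lay above. The elongase gene elo-2 rose by 0.71 (adjusted p = 0.0297) among 23 genes of fatty acid synthesis, while fat-7 was at 1.02 (adjusted p = 0.102) and fat-5 at 0.69 (adjusted p = 0.206). The fasting gene acs-2, an acyl-CoA synthetase, was at -1.32 (adjusted p = 0.0613). Without replicate 2 at 2 h, cyp-13A2, cyp-29A2, acs-17 and sqst-1 were not called (adjusted p = 0.248, 0.312, 0.204 and 0.235). The calls of cyp-14A2, elo-2 and ech-7 were lost without any of 7, 5 and 4 single arrays, 0 h arrays and that array among them (adjusted p up to 0.361, 0.529 and 0.492). With the replicate number as a block cyp-14A2 was not called (0.0564), while fat-7 and acs-2 were (0.0234 and 0.0162). None of these lists was called by the set test at 2 h (camera adjusted p = 0.565, 0.405, 0.495, 0.626 and 0.308).

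The count at 2 h depended most on replicate 2 of that time: it was 35 without it, 368 without replicate 1 at 2 h, 142 without replicate 2 at 0 h, and 414 with the replicate number as a block, a number that pairs the 0 h arrays with the 4 h arrays but not with the 2 h arrays. Of the 45 named calls, 11 held without any single array, those of C06B3.7, tsp-2, Y37H2A.14, F53B2.8, cgt-1, gst-22, C40H1.7, K02E7.6, nspe-1, ZK1290.5 and cpr-3, and 20 were lost only without replicate 2 at 2 h. Among the largest changes, those 20 include fbxc-58 (adjusted p = 0.0675), lec-11 (0.108), oac-6 (0.139), cutl-18 (0.213), gpdh-1 (0.0591) and ugt-63 (0.139), whereas amt-4 was also lost without any 0 h array (adjusted p up to 0.384) and with the replicate number as a block (0.0703). Without replicate 2 at 2 h the changes of K05B2.4, amt-4, asp-17 and elo-2 shrank to 0.93, -0.71, 0.69 and 0.47.

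**Figure D4:**
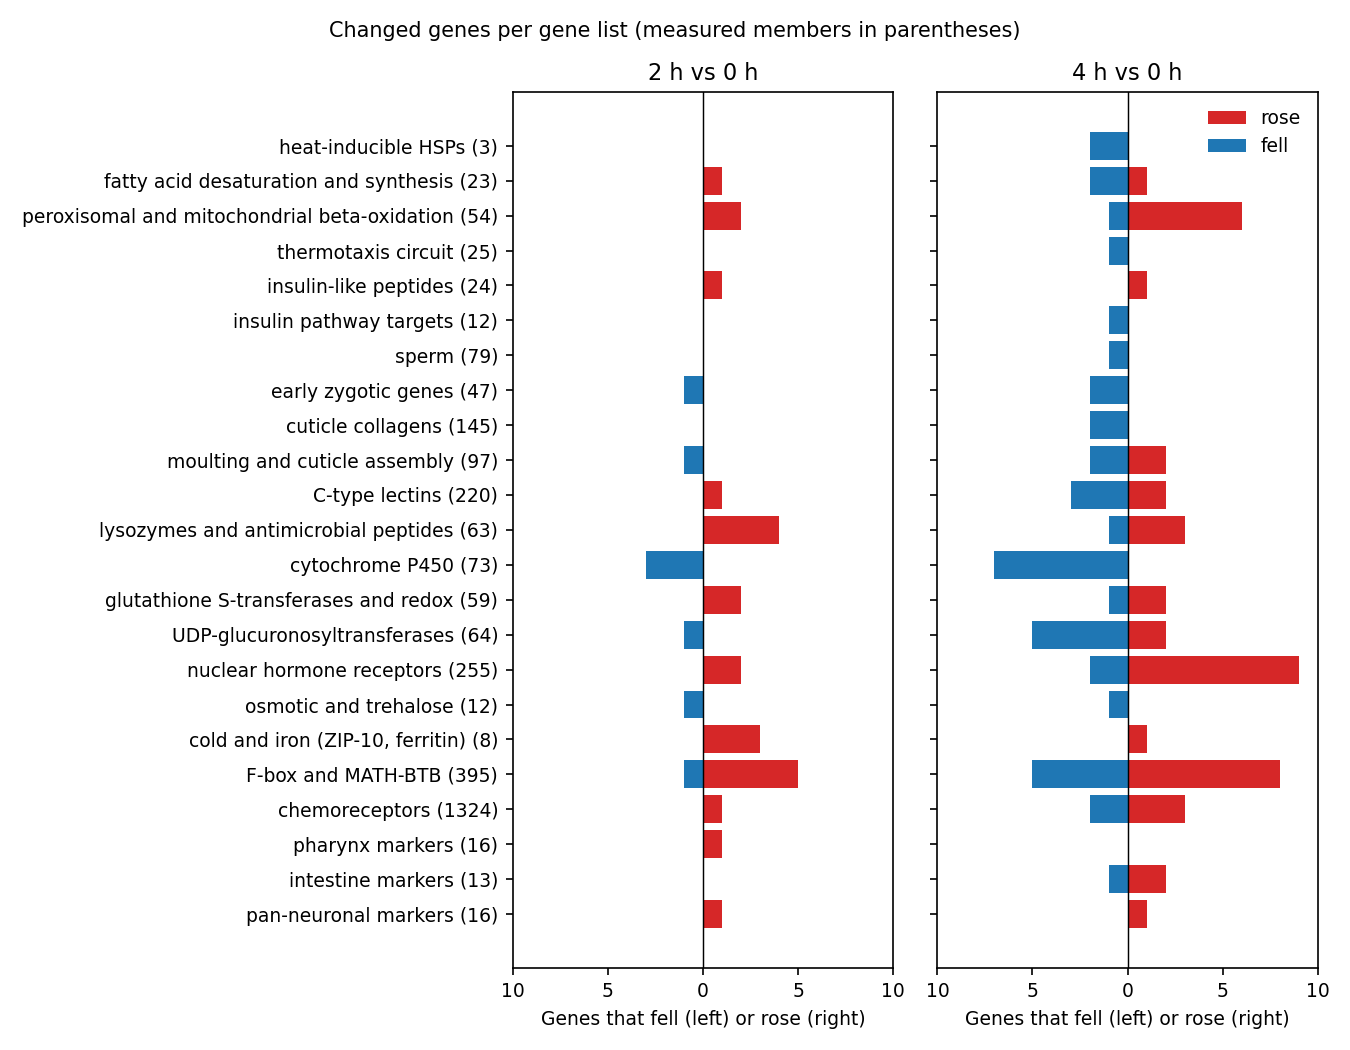
Number of genes that rose (red, to the right of 0) or fell (blue, to the left of 0) past the threshold at 2 h and at 4 h, for each gene list with a called member, measured members in parentheses. Cytochrome P450 genes show 3 falls at 2 h and 7 at 4 h without a rise, and beta-oxidation genes 2 and 6 rises.

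At 1 h, 0 of 22548 probe sets passed in limma, with 1448 at an unadjusted p under 0.05 against 1127 expected by chance and a smallest adjusted p of 0.227. Without replicate 1 at 1 h, 11 passed. The smallest p-values belonged to Y6D1A.2 (0.54, SE 0.0864), F59F5.3 (-0.51), C18H7.4 (-0.65), ZK1290.5 (-0.72, SE 0.125) and F54H12.8 (0.47), each with adjusted p = 0.227. Of these, Y6D1A.2 and ZK1290.5 were past the threshold at 2 h (1.10 and -1.05, adjusted p = 0.00011 and 0.00176) and at 4 h (0.74 and -0.83), and the other probe set of Y6D1A.2 at neither time (adjusted p = 0.168 and 0.221). The genes zip-10 (0.76, adjusted p = 0.433), cpr-3 (0.51, adjusted p = 0.295) and lys-7 (1.10, adjusted p = 0.349) did not pass. Among all genes 14.5% had both 1 h arrays outside the range of the 0 h arrays, against 13.3% by chance.

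The set test called 8 of 41 lists at 1 h. Neuropeptides lay higher (66 of 86 above 0, median 0.13, camera adjusted p = 7.42e-05), with adjusted p = 0.243 with an estimated correlation. Sperm genes lay lower (54 of 79 below 0, median -0.17, camera adjusted p = 0.000527), with adjusted p = 0.543 with an estimated correlation. Early zygotic genes and lysozymes lay higher (both camera adjusted p = 0.00501), with adjusted p = 0.243 and 0.267 with an estimated correlation. The same direction held for histones (camera adjusted p = 0.00773), fasting genes (0.0213) and pan-neuronal markers (0.0305), with adjusted p = 0.643, 0.243 and 0.243 with an estimated correlation. Proteasome subunits lay lower (camera adjusted p = 0.0112), with adjusted p = 0.543 with an estimated correlation. Adjusted over the list alone, 3 lysozyme and antimicrobial peptide genes, 1 pan-neuronal marker and 0 genes of the other 6 lists passed. Without replicate 2 at 1 h the calls of neuropeptides, early zygotic genes, histones, fasting genes, pan-neuronal markers and proteasome subunits were lost (adjusted p = 0.0531, 0.0992, 0.819, 0.2, 0.291 and 0.2), and without replicate 1 at 1 h that of lysozymes (0.0605). Without probe sets that can cross-hybridise the calls of sperm genes, histones, pan-neuronal markers, proteasome subunits, fasting genes and lysozymes were lost (adjusted p = 0.442, 0.916, 0.208, 0.185, 0.183 and 0.0844). The mean change then shrank for sperm genes (-0.201 to -0.056), histones (0.083 to 0.024), fasting genes (0.12 to 0.091) and lysozymes (0.105 to 0.083). It grew for pan-neuronal markers (0.108 to 0.167) and proteasome subunits (-0.067 to -0.075), whose losses do not show that cross-hybridisation made the signal. Early zygotic genes were not called without the dimmer 50% of probe sets (0.613), nor proteasome subunits and pan-neuronal markers after quantile normalization (0.0632 and 0.0553) or with the replicate number as a block (0.288 and 0.0794). Without replicate 3 or 4 at 0 h the calls of proteasome subunits and pan-neuronal markers were lost (0.0792 and 0.051, 0.0789 and 0.0658), without replicate 4 that of fasting genes (0.0658) and without replicate 2 that of histones (0.0557).

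**Figure D5:**
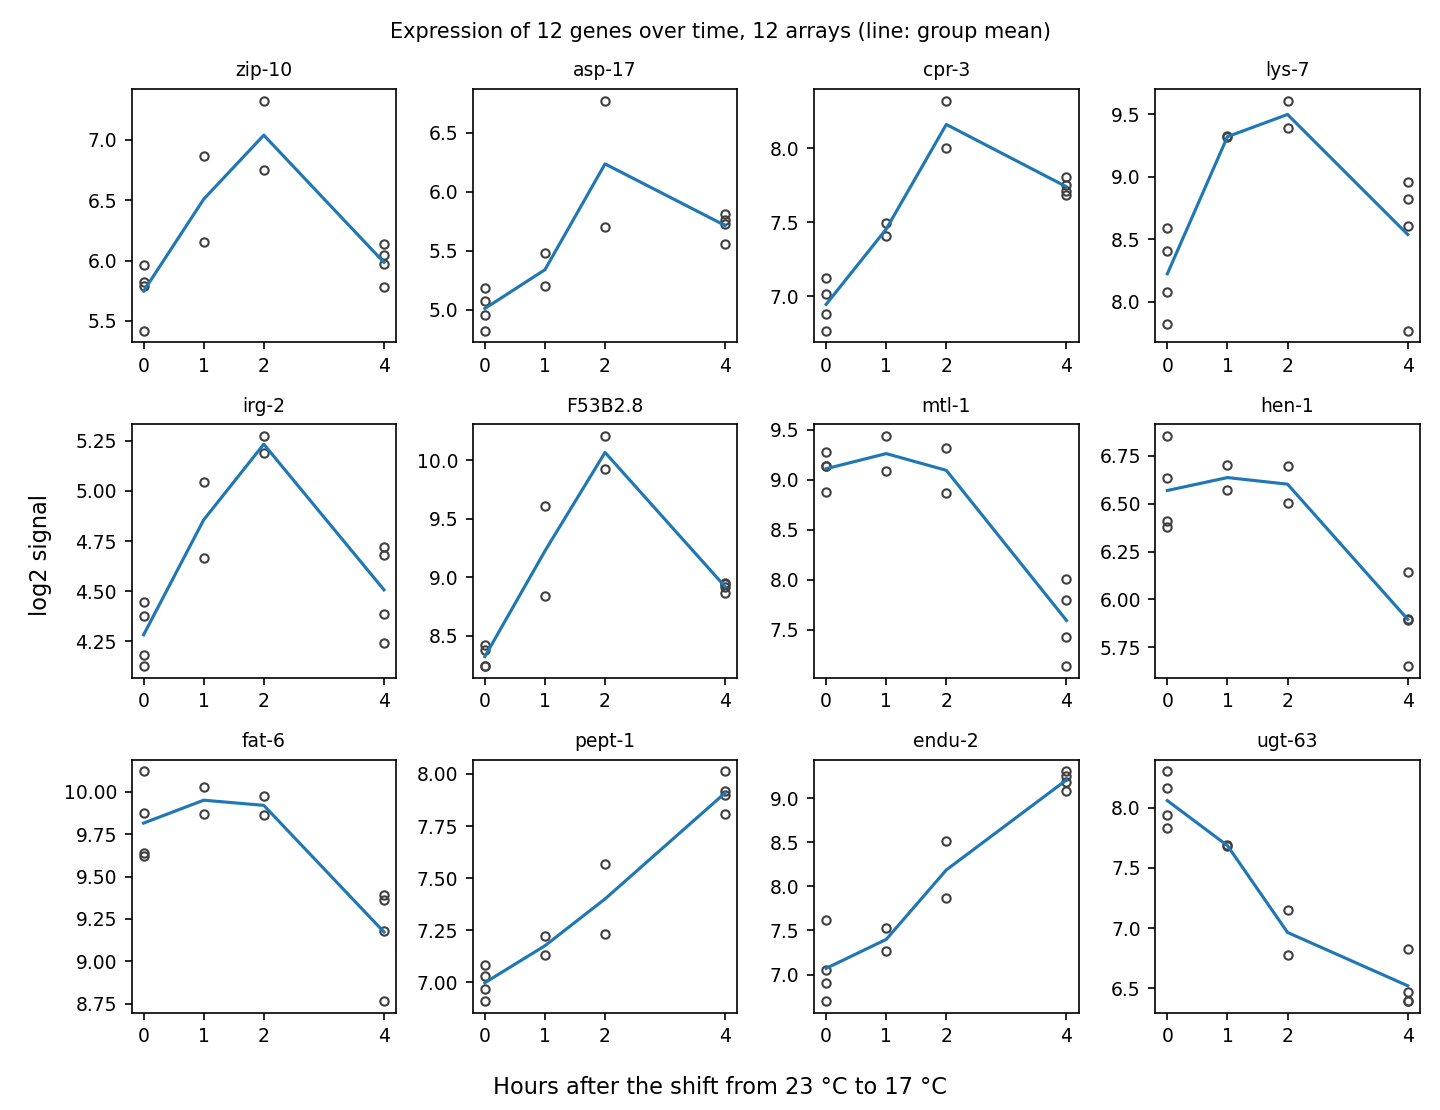
Log2 signal (vertical axis) of 12 genes on each of the 12 arrays (circles) against hours after the shift, with a line through the group means. The means of zip-10, lys-7, irg-2 and F53B2.8 were highest at 2 h, those of endu-2 and pept-1 at 4 h, and those of mtl-1, hen-1 and fat-6 were lower at 4 h than at the 3 earlier times.

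Between neighbouring times, 0 of 22548 probe sets passed from 1 h to 2 h in limma, with 1377 at an unadjusted p under 0.05 and a smallest adjusted p of 0.155, and 24 passed without replicate 1 at 2 h. From 2 h to 4 h, 13 passed, 6 higher and 7 lower, with 2409 at an unadjusted p under 0.05. The metallothionein gene mtl-1 fell by 1.499 in that step (SE 0.213, adjusted p = 0.0364) and ent-4, a nucleoside transporter gene, rose by 0.88 (SE 0.101, adjusted p = 0.0186). The transthyretin-like genes ttr-29 and ttr-23 had risen by 1.07 and 1.08 at 2 h and fell by 1.08 and 0.87 from 2 h to 4 h, but the 2 h call of ttr-29 was lost without replicate 2 at 2 h (adjusted p = 0.0675). The count of 13 was 0 without replicate 2 or 3 at 4 h, replicate 3 at 0 h or replicate 2 at 2 h, and 28 without replicate 1 at 2 h. With the replicate number as a block it was 70, of which 16 were higher and 54 lower. A moderated F test over the 3 changes from 0 h called 400 probe sets. That count was 266, 247, 242 and 262 without replicates 1, 2, 3 and 4 at 0 h, and 241 and 215 without replicates 2 and 3 at 4 h.

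Calls at both 2 h and 4 h numbered 83 higher and 51 lower, with 0 in opposite directions. Of the 518 called at 4 h, 499 had the same sign at 2 h and 436 at 1 h. These comparisons use the same 0 h arrays, which gives shared directions without any effect, and no count without effect was made for these numbers. Across genes, which are not independent replicates, the log2 changes at 2 h and 4 h correlated at r = 0.581. Simulations without any effect, with a simulated 0 h group shared by both times, gave 0.408. They gave 0.346 where simulated 0 h and 4 h arrays of a number shared part of their deviations. With the replicate number as a block r was 0.519, against 0.314 in such simulations with the block. The average r was 0.361 (range 0.267 to 0.432) over 6 splits of the 0 h arrays into separate controls. For 1 h and 4 h, r was 0.396 against 0.408 simulated without and 0.347 with the pairing, and it averaged 0.148 with separate controls. Without replicate 2 at 1 h, r was 0.214. The simulations drew each probe set independently, so their r follows from the group sizes and the pairing alone. They leave out noise that genes share on an array, so no conclusion about 0.581, 0.519 or 0.396 is drawn from them.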

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

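The tests of 1 outlying 2 h array, of array scaling, of a single transcript and of age or handling were chosen only after the result was seen; the count of splits and the test of a batch were set beforehand.

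In 7 of 112 groups of 4 arrays, 1 array lay far from the other 3 by Dixon's ratio, against 5.6 expected by chance. At 0 h these were K05B2.4 (ratio 0.871, replicate 1 at 3.43 against 4.13 to 4.24), hsp-90 (0.878, replicate 2 at 13.12 against 13.19 to 13.2) and gcy-8 (0.868, replicate 1 at 3.76 against 3.89 to 3.91). At 4 h they were anmt-3 (0.972, replicate 4 at 6.34 against 5.69 to 5.70), hsp-16.2 (0.854, replicate 1 at 2.94 against 3.92 to 4.08), hsp-70 (0.949, replicate 2 at 3.42 against 3.14 to 3.16) and gcy-18 (0.91, replicate 1 at 5.20 against 4.75 to 4.79). The calls of K05B2.4, anmt-3 and hsp-16.2 at 4 h held without any single array.

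The change from 0 h differed between 2 h and 4 h for 13 probe sets by the limma test of 4 h against 2 h (adjusted p from 0.0186 to 0.0483). Lower at 4 h than at 2 h were mtl-1 (-1.499), F53B2.8 (-1.15), ttr-29 (-1.08), ttr-23 (-0.87), T12A2.3 (-0.72), C12D5.9 (-0.69) and F25D1.5 (-0.49). Higher at 4 h were F42A10.7 (0.92), ent-4 (0.88), nhr-31 (0.63), ltah-1.2 (0.58), Y39B6A.41 (0.57) and 1 probe set shared by 2 F-box genes (0.66). Of the 12 single-gene probe sets, F53B2.8, ttr-29, ttr-23 and F25D1.5 had risen at 2 h (1.74, 1.07, 1.08 and 0.52) and Y39B6A.41 had fallen (-0.48, adjusted p = 0.0166, with 0.09 at 4 h), while mtl-1, T12A2.3, ent-4, F42A10.7 and ltah-1.2 were called at 4 h and not at 2 h. The shared F-box probe set had fallen at 2 h as well (-0.59), and the 2 h calls of it, Y39B6A.41 and ttr-29 were lost without replicate 2 at 2 h (adjusted p = 0.257, 0.28 and 0.0675). The count of 13 was 7 after quantile normalization and 0 without replicate 2 at 2 h.

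The count of 518 probe sets at 4 h was set against other splits of the 8 arrays of 0 h and 4 h into 4 and 4. Leaving the pairing aside, the real split was the only 1 of 35 to reach it, a share of 0.029, and the highest other gave 33, with replicates 1 and 2 against replicates 3 and 4. Since the replicate numbers pair these arrays, the nearer comparison is with the splits that part all 4 pairs. These are 8, too few for a share under 0.05, and the real one gave 518 where the highest other gave 0. Time, temperature, age and handling all follow the real split and stay open together.

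Rises at 2 h could come from a technical batch holding both the 1 h and the 2 h arrays, or from 1 outlying 2 h array. For the 100 probe sets with the smallest p for a rise when a 2 h array was left out, that array exceeded the mean of the 1 h arrays by a median of 0.265 (SE 0.036) in 1 case and 0.4 (SE 0.067) in the other, which argues against an equal shift of both times as the whole cause. These errors are over probe sets of single arrays. On the chosen probe sets the 1 h arrays lay 0.327 and 0.333 above 0 h. The same 0 h arrays helped to choose these probe sets, which raises that difference even without any change at 1 h. How much of the rise a shared batch could still give is therefore not known. With 100 probe sets chosen on 1 of the 2 h arrays and 2 of the 0 h arrays, 80 to 95 lay above both remaining 0 h arrays in the other 2 h array over the 12 choices, against 30.4% to 37.1% of all probe sets, which argues against a single outlying array, although only 35 calls were left without replicate 2 and 368 without replicate 1. The hour of sampling and a batch of the 2 h arrays alone, confounded with it, stay open.

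Of 7 heat-inducible chaperone probe sets 6 fell at 4 h, with a median of -0.88 over the 7. A single transcript read by every probe set would move 1 sequence family, but 2 of 3 HSP70-family probe sets fell besides 4 of 4 of the hsp-16 family, although the HSP70-family signals lay near or under the lower quartile at 4 h. Those 2 HSP70-family probe sets are assigned to the same 2 genes. Scaling of whole arrays keeps the order of probe sets within an array, and 6 of the 7 ranked lower on every 4 h array than on every 0 h array. Since the arrays had been brought close to one distribution, these ranks restate the falls and are no separate support. The 0.1 expected by chance holds for random array labels, not for scaling. The falls differed by up to 2.45 (SE 0.273), between the largest and the smallest of the 7, picked after they were seen. The smallest, of hsp-70, began near the lower quartile (3.56 at 0 h), so no conclusion is drawn from this difference. Array medians ranged over 0.0683 log2 units, which argues against an equal shift of the deposited values as the whole cause. Less induction of heat-shock genes at the cooler temperature may account for the fall and stays open too. Time since hatching or handling cannot be told apart from it, since 0 arrays came from animals kept at 23 °C for the same 4 h.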

How the results depend on the processing

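All alternatives were chosen before the values were seen, and log2(value + 16) was not run, since the values are already log2. The count at 4 h stayed within 378 to 699 over the other settings, and 218 were at least 1.5-fold; the 8 arrays alone gave 570, or 634 with the replicate block. The count at 2 h was 414 with the fixed replicate block and 169 to 315 otherwise. From 2 h to 4 h the count was 7 after quantile normalization (28.6% higher, against 46.2% as reported), 8 without probe sets that can cross-hybridise, 39 with trend and robust variances, and 70 with the fixed block. The correlation of 2 h and 4 h was 0.519 with that block. The block changed no other count by more than 1.5 times (615 at 4 h, 583 in the F test; 699 and 546 as a random block). Besides the calls named above as lost with it, it ended those of aex-3 and nhr-183 at 2 h (adjusted p = 0.0876 and 0.0553) and of ptr-15 and grd-7 at 4 h (0.0763 and 0.0963). As a fixed block over the 12 arrays it gave calls to lipl-2, nlp-31, cav-1 and cdh-3 at 4 h (0.0485, 0.0452, 0.0485 and 0.0373) and to dnj-13, flp-18, dod-3, col-95 and col-122 at 2 h besides fat-7 and acs-2, and as a random block to unc-23 at 4 h (0.039). It also gave calls to the lists of insulin targets and muscle markers at 1 h and of histones and intestine markers at 2 h. Called lists numbered 14 at 1 h and 11 at 2 h without the dimmer 50% of probe sets, 3 at both times without cross-hybridising probe sets, and 15, 12 and 11 at 1 h, 2 h and 4 h with all probe sets of a list. With an estimated correlation 0 were called at any of the 3 times. Fry's directional test called 0, 3 and 7 lists and its mixed test 1, 23 and 20. The 3 at 2 h were cytosolic chaperones, lysozymes, and cold and iron genes. In simulated data without correlated genes, a list of 30 genes was shifted by 0.3 log2 units at 4 h. Its camera adjusted p was 4.58e-40 with the preset and 6.54e-05 with an estimate, so an estimate weakened the test without correlated members. Other causes were not tested.

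Without 1 array in turn, counts ran from 0 to 11 at 1 h, 35 to 368 at 2 h, 324 to 543 at 4 h, 0 to 24 from 1 h to 2 h, 0 to 28 from 2 h to 4 h and 215 to 457 in the F test. Called lists ran from 2 to 10 at 1 h, 4 to 10 at 2 h and 5 to 10 at 4 h. The correlation with 4 h ran from 0.214 to 0.447 for 1 h and from 0.508 to 0.615 for 2 h. Where a time kept 1 array, that array was assumed to vary like the other groups. For calls of named genes, 268 of 2593 recomputed values lost the call and 0 changed direction; 70 of 4923 values of uncalled genes gained one. For 20 called lists, 81 of 510 values lost the call and 0 changed direction.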

Other observations

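The comparison of gene families by name, with its counts without single arrays, was chosen only after the result was seen.

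Regulatory gene families and chemoreceptors also had members that changed at 4 h, where 425 of 17118 genes were called in all. Of 255 nuclear hormone receptor genes, 9 rose and 2 fell (20 when adjusted over the list alone, camera adjusted p = 0.0759). The gene nhr-47 rose by 0.53 (adjusted p = 0.00231, its other probe set 0.24 with adjusted p = 0.315) and nhr-203 by 0.38, while nhr-249 and nhr-137 each fell by 0.63. At 2 h, nhr-131 (0.68) and nhr-183 (0.55) rose. Of 395 F-box and MATH-BTB genes, whose products include substrate adaptors of ubiquitin ligases, 8 rose and 5 fell at 4 h (15 when adjusted over the list alone, camera adjusted p = 0.663). Examples were fbxa-162 (0.89), bath-26 (0.68), fbxa-98 (0.56) and bath-47 (0.52). Of 1324 chemoreceptor genes, 3 rose and 2 fell (4 when adjusted over the list alone, camera adjusted p = 0.694), with str-245 at 0.84, sre-44 at 0.54 and srh-237 at -0.94. This is a lower share than over all genes. The median signal of the list was 2.47, under the lower quartile of every array (3.53 to 3.64). The gene srsx-34 rose by 0.62, but its other probe sets changed by 0.17 and 0.15 and were not called. Of 97 moulting and cuticle assembly genes, 2 rose and 2 fell (5 when adjusted over the list alone, camera adjusted p = 0.285): ptr-15 (0.52), ptr-24 (0.41), cutl-18 (-0.88) and grd-7 (-0.43). Without some single arrays nhr-137, ptr-15, cutl-18 and grd-7 were not called at 4 h (adjusted p up to 0.0675, 0.118, 0.088 and 0.146), nor nhr-131 and nhr-183 at 2 h (0.298 and 0.158). With the replicate number as a block ptr-15, grd-7 and, at 2 h, nhr-183 were not called over the 12 arrays (0.0763, 0.0963 and 0.0553), nor ptr-15 and grd-7 over the 8 of 0 h and 4 h (0.106 and 0.058).

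Families of genes that share a name stem were compared with the 17118 genes tested by one-sided Fisher's exact tests, 660 in all. Cytochrome P450 genes fell at 4 h more often than other genes (7 of 73 against 0.759 expected, adjusted p = 0.00706). That call held without replicate 2 at 0 h, either 1 h array or replicate 2 at 2 h (adjusted p up to 0.0467). It was lost without any of the other 8 arrays, with 3 to 6 genes left and adjusted p from 0.0647 (replicate 1 at 2 h) to 1 (replicate 3 at 4 h). Genes of the lys family rose at 2 h more often (3 of 10 against 0.0707 expected, adjusted p = 0.0132). This was lost without any of 10 arrays (adjusted p from 0.222 to 1) and held only without replicate 1 or 4 at 4 h; without replicate 2 at 2 h or replicate 1 or 2 at 0 h, 0 of the 3 limma calls were left. Families cest and ugt missed the threshold at 4 h (4 of 32 and 5 of 64 fell, adjusted p = 0.0713 and 0.0881). Without replicate 1 or 3 at 4 h, cest was called (Fisher adjusted p = 0.0339 and 0.0397). The ugt family was called without replicate 1 or 4 at 4 h or replicate 2 at 0 h (0.0339, 0.000707 and 0.0307). Without other single arrays adjusted p reached 0.318 and 0.305. The cytochrome P450 call thus does not set that family apart from cest and ugt. These tests treat genes as independent, which members of a family are not.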
